A study of Homo sapiens with 2 samples.

How the data were processed

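Expression was measured in 2 stable derivatives of THP-1, a human monocytic leukaemia cell line. Per the labels, 1 derivative carries a short hairpin RNA (shRNA, a transcript processed into a small RNA that directs degradation of a matching mRNA) against LY6E and is called shLY6E here. The other carries a scrambled shRNA and is called shCtrl. Each group had 1 array, and the groups were taken from the sample titles. Per the labels' protocols, both derivatives grew under puromycin, total RNA was taken with Trizol and cleaned on a column with DNase, and biotin-labelled cRNA was made with an Ambion MessageAmp kit for Illumina arrays.

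The deposited unnormalized table gave an intensity and a detection p-value for each of 47321 probes on each array, per the file headers. The intensities were linear and never below 0, with a median of 97.5 in shLY6E and 116 in shCtrl, so neither background subtraction nor scaling between arrays showed in them. The detection p-values in the deposited table moved in steps of 1 in 770, which is how a rank among negative control probes behaves. A separate deposited table held the authors' processed intensities. From the values, these were on a linear scale, background-subtracted and put on a common distribution: the median was 6.14 in both columns, and 25.5% of values lay below 0. Across probes their Spearman correlation with the same array's unnormalized intensity was 1.0, against 0.85 with the other array's. The scanner software and the authors' methods of background subtraction and normalization are not given in the sources used here. No column of the tables was left without a sample (0 columns).

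The unnormalized intensities were background-corrected with the normexp model, with the background estimated through the detection p-values and an offset of 16 added, then quantile-normalized between the 2 arrays and put on the log2 scale (limma 3.58.1 in R 4.3.3). The later steps used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. A probe was called detected at a detection p-value under 0.01, and a gene was kept if a probe of it was detected on at least 1 array. The kept probe with the highest mean log2 intensity stood for the gene. For a gene detected on 1 array only, the difference is a bound against the higher of its own value and the lowest normalized intensity among detected probes on the other array, and is written "at least N-fold". The offset and the background shrink differences of dim genes. Folds near the detection limit also depend on noise and on the background estimate. They may lie below or above the ratio of the RNAs, and genes picked for the largest folds may be overstated.

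Probes were named through the platform annotation, in which 30113 probes had 1 gene symbol, 8 had several and 17200 were not listed with a gene. Of the probes with 1 symbol, 30074 matched a RefSeq gene table of assembly GRCh38.p14 by Entrez ID, and 0 symbols needed an update. The named probes covered 20046 genes. The same table gave each gene's chromosome and the order of neighbouring genes. No coordinates were taken from it, since the build behind the probes is not given in the sources used here. XIST and Y-linked genes were not reported.

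With 1 array per group there is no spread between samples, so no p-value, standard error or count of significant genes was computed. Genes were counted at a difference of at least 2-fold (1 on the log2 scale). Each of 28 gene lists was described by the median log2 difference of its detected genes and by that median's percentile among 10000 random lists of the same size, drawn from genes of similar mean intensity (up to 100 ranks away on either side). Lists with fewer than 3 detected genes got no median. The lists, the thresholds, the rule for named genes and 8 of the 10 alternative settings were fixed before the data were examined. The rule named LY6E, the 12 genes highest and the 12 lowest in shLY6E among genes detected on both arrays, the 5 largest bounds in each direction, up to 4 members of each list by size of difference, and CD14, TLR4, LY96, LBP and MYD88. Symbols that are placeholders or clone names were passed over. Genes named outside this rule, such as IL1RN and SOD2, were chosen after their values were seen.

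The 8 alternatives fixed beforehand were no background correction, scaling to a common median in place of quantile normalization, an offset of 50, a detection p-value under 0.05, detection on both arrays, no detection filter, the mean over a gene's probes, and the authors' processed intensities. For the last, values below 0 were set to 0 and 16 was added before taking log2, a floor chosen once the scale of that table was known. The other 2 alternatives, the measured difference in place of the bound and leaving out the genes of chromosome 10, were chosen after seeing the data.

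The steps were tested on simulated arrays of the shLY6E and shCtrl comparison, built from the real intensities with an assumed log2 noise SD of 0.1, which was not measured. Among 12297 simulated genes, 97 of 100 genes changed 4-fold and 92 of 100 genes changed 2.83-fold came out at least 2-fold apart, with 0 in the wrong direction. None (0) of 12097 unchanged genes did so. With noise this small, the count of 0 was all but fixed beforehand and does not bound false 2-fold calls in the real arrays. There, the shLY6E minus shCtrl difference had an SD between probes of a gene of 0.26. The changed genes were drawn from those detected on both real arrays, so recovery of other genes was not tested. Of 100 unchanged lists of 26 genes, 5 fell outside the central 95% of random lists, and a list shifted by 0.5 came out at percentile 100. That shift was added to the finished differences, so it tested only the ranking among random lists.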

Results

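The data collected were 2 single-colour Illumina arrays of total RNA, 1 from THP-1 cells with an shRNA against LY6E (shLY6E) and 1 from THP-1 cells with a scrambled shRNA (shCtrl). Of 47321 probes, 16378 (34.6%) were detected on the shLY6E array and 16283 (34.4%) on the shCtrl array. These named 10565 genes, of which 9364 were detected on both arrays, 571 on the shLY6E array only and 630 on the shCtrl array only. Differences are given as shLY6E minus shCtrl on the log2 scale of normalized intensity, or as the fold this corresponds to. With 1 array per group (n = 1) there was no replicate check of any difference, and the number of arrays limits the precision. The spread available was that between probes of a gene, read on the same 2 arrays. Across 2254 genes with at least 2 probes detected on both arrays, the shLY6E minus shCtrl difference had a within-gene SD of 0.26. The Pearson correlation between the 2 probes across these genes was 0.69.

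LY6E, which encodes an interferon-inducible, GPI-anchored surface protein of the LY6 family, was 3.67-fold lower in the shLY6E array. Its deposited intensity was 253 in shLY6E and 1049 in shCtrl, and its normalized log2 intensity was 7.78 and 9.65, a difference of -1.88 or 27.3% of the control level. It ranked 15 from the lowest of the 9364 genes detected on both arrays, and 0 of 500 genes of similar intensity were as low. Its 20 nearest detected neighbours on chromosome 8 had a median difference of -0.10, and the lowest of them stood at -1.12. LY6E was read by 1 detected probe. Of the 23 genes of the LY6 and uPAR family list, 6 were detected, with a median of -0.42 at percentile 3.76 of random lists, LY6E itself included. The median was -0.14 (percentile 35.0) over genes detected on both arrays and -0.0039 (percentile 57.1) with no detection filter. Besides LY6E, PLAUR, the urokinase receptor, was 1.86-fold higher, and LY6G5C and LYPD6 were at least 1.61-fold and 1.40-fold lower.

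The comparison of shLY6E with shCtrl asked which transcripts differ when LY6E is silenced in a monocytic line. Among genes detected on both arrays, the highest in shLY6E were CXCL8, IL4I1, SPP1, MFNG and CD14. CXCL8, which encodes the neutrophil chemoattractant interleukin-8, was 19.9-fold higher, with a deposited intensity of 1209 against 174. IL4I1, an amino acid oxidase of antigen-presenting cells, was 15.1-fold higher, and SPP1, which encodes osteopontin, was 13.9-fold higher. MFNG, a glycosyltransferase that modifies Notch receptors, was 12.1-fold higher, and CD14, the lipopolysaccharide co-receptor, was 10.3-fold higher. In shLY6E the deposited intensities of IL4I1, SPP1, MFNG and CD14 were 658, 733, 525 and 512. In shCtrl they were 146, 159, 145 and 153, near the lowest detected there, 129. The lowest among genes detected on both arrays were DACH1, a transcriptional regulator, at 9.94-fold lower, and MSRB3, a methionine sulfoxide reductase, at 7.60-fold lower. In shLY6E the intensities of DACH1 and MSRB3 were 119 and 109, near the lowest detected there, 106. Folds of genes this dim on 1 array depend on the background correction.

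In all, 240 genes were at least 2-fold higher and 269 at least 2-fold lower in shLY6E, so that 47.2% of these 509 genes were higher. Without background correction the counts were 97 and 65, and 59.9% were higher. Differences of at least 4-fold were found for 47 genes in the higher direction and 14 in the lower. TNF, IGFBP3, SLC2A6, VCAN, CCL3, CCL3L1 and ORM1 completed the 12 highest among genes detected on both arrays, between 7.03-fold and 8.74-fold. In shCtrl the deposited intensities of IGFBP3, VCAN and ORM1 were 140, 139 and 129, also near the lowest detected there. CCL4L1 was detected in shLY6E only and at least 33.5-fold higher, MMP9, a gelatinase, at least 12.5-fold, EPB41L3 at least 8.37-fold, complement C3 at least 7.92-fold and TNFAIP6 at least 7.48-fold. CCL3, CCL3L1 and CCL4L1 belong to near-identical gene copies, as do ORM1 and SNAR-A1, so their probes may read more than the named gene and these values are uncertain. The laminin chain gene LAMA5 was 5.17-fold lower, MYBPH 5.10-fold, PYROXD2 4.87-fold, SUSD3 4.78-fold, SNAR-A1 4.76-fold, LRRC26 4.74-fold and the pro-apoptotic gene BIK 3.92-fold. UGT3A2, LZTS2 and BEGAIN lay between 4.01-fold and 4.48-fold lower. TACC2, WNT7B, DLX3, SAMD11 and ATP8B3 were detected in shCtrl only, at least 6.0-fold, 5.17-fold, 5.07-fold, 3.67-fold and 3.34-fold lower. Of 80 genes at least 2-fold apart with another probe detected on both arrays, that probe had the same direction for 76 and was at least 1.5-fold apart for 62. The less bright probes of MSRB3 gave -3.10 and -0.04, both bounds.

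**Figure D1:**
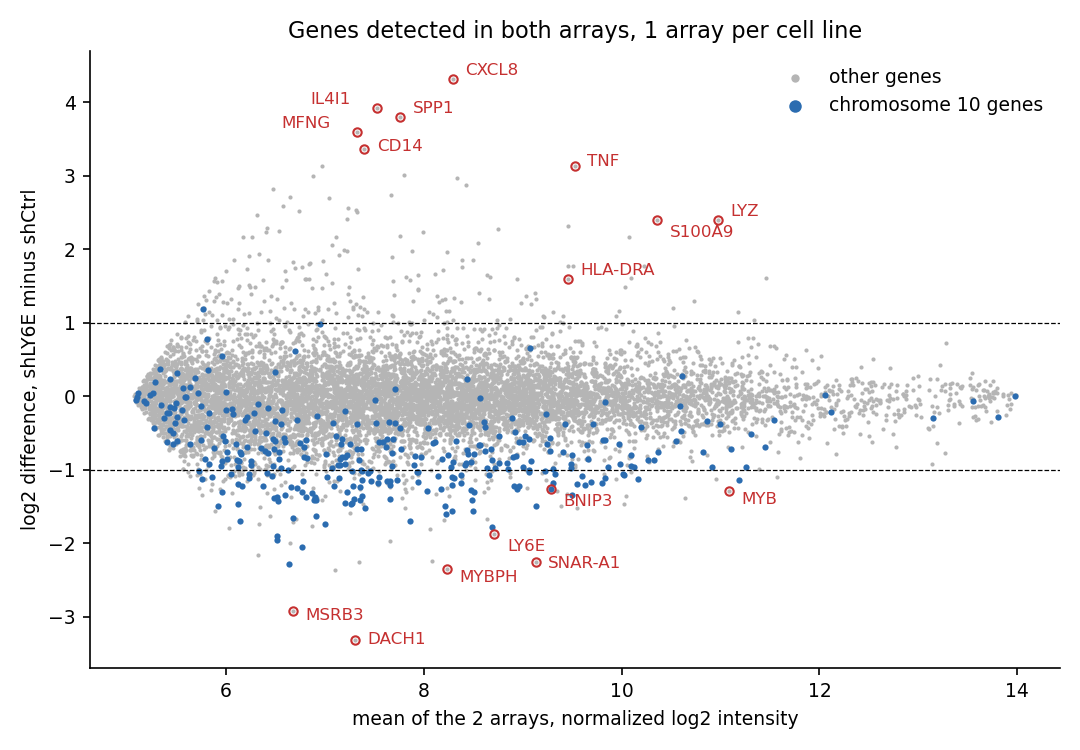
Log2 difference (shLY6E minus shCtrl) against the mean normalized log2 intensity of the 2 arrays for genes detected on both, 1 point per gene. Blue points are genes of chromosome 10, red circles mark named genes, and dashed lines mark 2-fold; CXCL8 lies at 4.32, DACH1 at -3.31 and LY6E at -1.88.

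Inflammatory cytokines and NF-kB target genes were higher in shLY6E. Of 26 detected members of this list, 17 were at least 2-fold higher, 0 were at least 1.5-fold lower, and the remaining 9 lay between -0.29 and 0.90. The list median was 1.41, at percentile 100 of random lists, whose central 95% ran from -0.20 to 0.13, and was 0.82 without background correction. TNF, a central inflammatory cytokine, was 8.74-fold higher (deposited intensity 1863 against 391), and the chemokine gene CCL3 was 7.82-fold higher. TNFAIP6, which encodes a hyaluronan-binding protein induced by TNF, was detected in shLY6E only. Random lists draw genes independently, so the percentile of a list whose members share regulators is more extreme than for unrelated genes.

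Among the genes of CD14 and TLR4 signalling, CD14 had the largest difference, 3.36, and its other probe gave a bound of 2.33. TLR4, the lipopolysaccharide receptor, was close to the detection limit with a difference of -0.23, and the adaptor gene MYD88 differed by 0.12. LY96, which encodes the TLR4 partner MD-2, and LBP, which encodes lipopolysaccharide-binding protein, were not detected on either array. IRAK2, a kinase downstream of MYD88, was 6.52-fold higher, the NF-kB subunit gene RELB 3.88-fold and TRAF3, a signalling adaptor, 3.59-fold. Of 26 detected members, 6 were at least 2-fold higher, 0 at least 2-fold lower and 16 within 1.5-fold. TICAM2, at -0.68, was the 1 member at least 1.5-fold lower and was chosen after its value was seen. This list shares NFKBIA with the inflammatory list, and CD14 with the lists of monocyte markers and GPI-anchored proteins. The list median was 0.21, at percentile 99.8, and was 0.13 without background correction. It was 0.32 with a detection p-value under 0.05 or with measured differences in place of bounds.

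Of 25 detected monocyte and macrophage markers, 7 were at least 2-fold higher, 0 at least 1.5-fold lower and 16 within 1.5-fold, with a median of 0.45 at percentile 100. The median was 0.21 without background correction and 0.28 with offset 50. Besides CD14, the proteoglycan gene VCAN was 7.95-fold higher, the lysozyme gene LYZ 5.25-fold and the calprotectin subunit gene S100A9 5.24-fold. The other probe of LYZ gave 1.36. In the list of immature myeloid and granule genes, the median was -0.33 at percentile 0.295. Of its 13 detected members, 5 were at least 1.5-fold lower and 1 at least 1.5-fold higher. MYB, a transcription factor of progenitor cells, was 2.46-fold lower, the granule protease gene PRTN3 1.61-fold lower and CAMP at least 1.60-fold lower, while the receptor kinase gene FLT3 was 2.15-fold higher. Scaled to a common median, this list stood at -0.10 and percentile 4.89, inside the central 95%, as it also did with no detection filter (-0.11, percentile 20.03) and with a detection p-value under 0.05 (percentile 4.22).

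Of 10 detected genes of MHC class II, 3 were at least 2-fold higher and 0 at least 1.5-fold lower, with a median of 0.61 at percentile 100. These include HLA-DRB1, HLA-DRB3, HLA-DRB4 and HLA-DRB5, at 0.53, 0.45, 0.52 and 0.70. Their probes may read one another's transcripts, so they may not be separate readings and the percentile may be too extreme. HLA-DRA was 3.01-fold higher, HLA-DPA1 2.98-fold and the invariant chain gene CD74 2.21-fold, while HLA-DMA, a peptide loading factor, was 1.90-fold higher. Of 13 genes of MHC class I, 2 were at least 1.5-fold higher, HLA-F at 1.66-fold and HLA-B at 1.61-fold, and 11 were within 1.5-fold, 3 of them below 0. The class I median was 0.36, at percentile 99.98. Probes of HLA genes can read related loci, and the other probe of HLA-F gave -0.12. TAP2 and PSMB9, of the peptide supply pathway, were 1.43-fold and 1.36-fold higher, and the other probe of TAP2 gave -0.39.

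Genes of the interferon-stimulated list were lower as a group in shLY6E, 33 of them below 0 and 6 above. Of 39 detected members, 8 were at least 2-fold lower, 15 at least 1.5-fold lower and 0 at least 1.5-fold higher, with a median of -0.41 at percentile 0, or -0.25 without background correction. IFIT1, an antiviral RNA-binding protein gene, was 2.82-fold lower, the antiviral GTPase genes MX1 and MX2 were 2.48-fold and 2.31-fold lower, and IFITM3 was 2.19-fold lower. IFITM3 has close relatives that its probe may also read. LY6E, itself interferon-inducible, was not on this list, which does not cover all interferon-inducible genes. Of the 39 genes 3 lie on chromosome 10, IFIT1 among them, and without these the median was -0.40, again at percentile 0.

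Mitosis genes were lower as a group: 26 of 26 detected members were below 0, 7 of them by at least 1.5-fold, with a median of -0.40 at percentile 0. The kinesin gene KIF11 was 2.67-fold lower, the proliferation marker MKI67 2.36-fold and the cyclin-dependent kinase gene CDK1 1.66-fold, and these 3 lie on chromosome 10. KIF20A, another kinesin gene, lies on chromosome 5 and was 1.73-fold lower. Without chromosome 10 the median was -0.36, at percentile 0. Genes of S phase and DNA replication had a median of -0.13 at percentile 11.7, with 4 of 23 at least 1.5-fold lower and 1 higher. Averaged over each gene's probes, the median was -0.035, at percentile 49.3. MCM10, on chromosome 10, was 2.56-fold lower, the licensing factor gene CDT1 1.77-fold lower, and RRM2, a ribonucleotide reductase subunit gene, 1.74-fold higher. Probes of MCM7 disagreed in sign, from -0.63 for the brightest to 0.98.

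**Figure D2:**
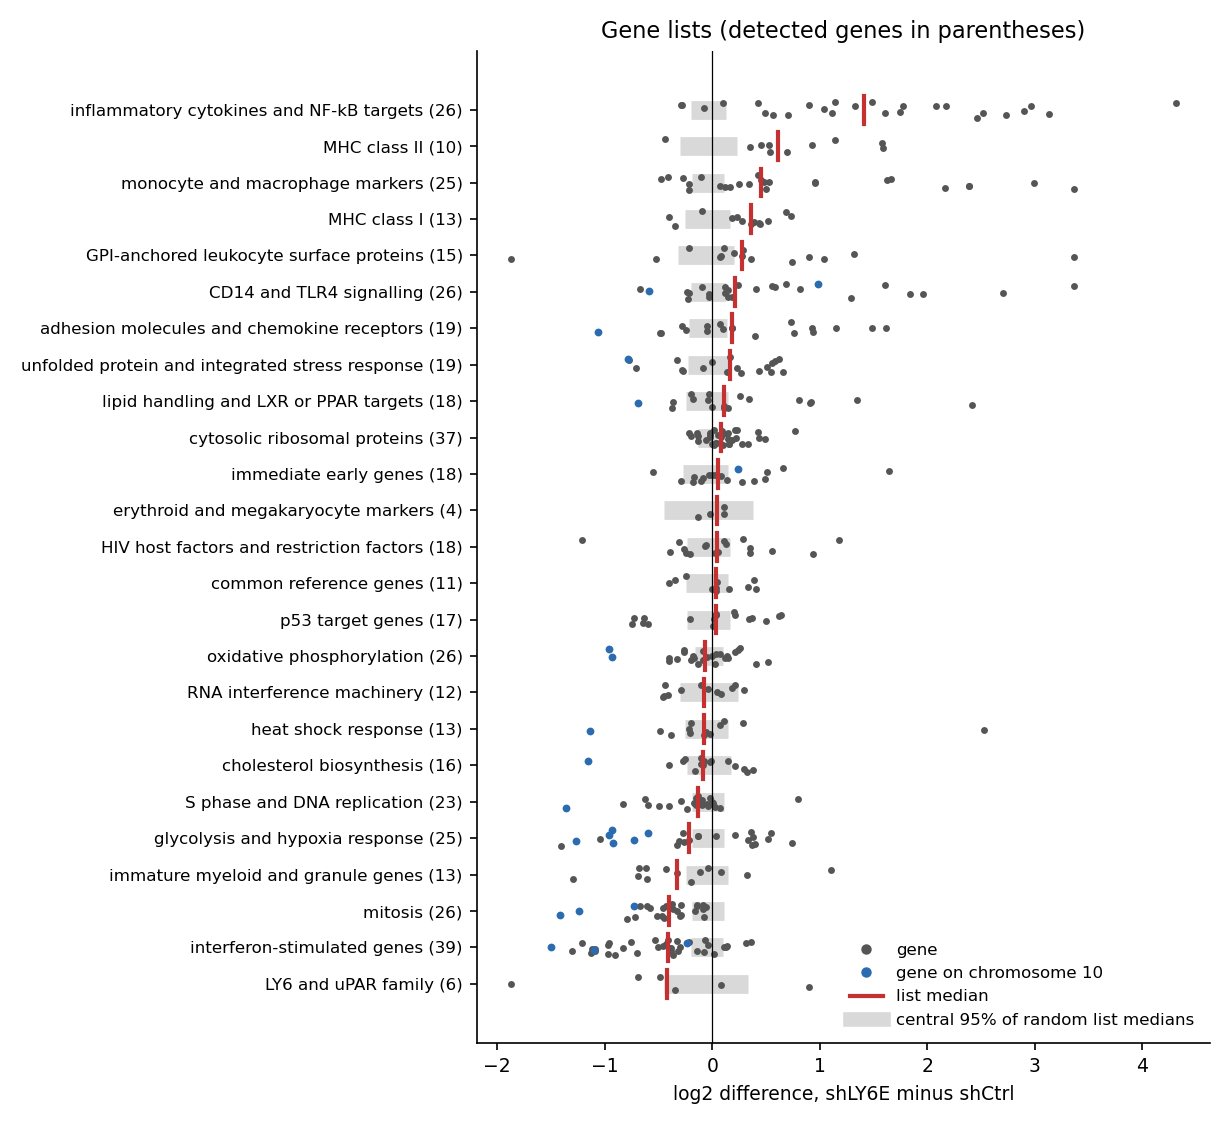
Log2 difference (shLY6E minus shCtrl, x axis) of each detected gene of the 25 lists with at least 3 detected genes, with bounds for genes detected on 1 array. Red bars are list medians, grey bands the central 95% of random list medians and blue points genes of chromosome 10; inflammatory cytokines and NF-kB targets stand highest at 1.41, and among lists outside their band interferon-stimulated genes stand lowest at -0.41.

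Genes of chromosome 10 were lower in shLY6E along the whole chromosome, a grouping looked at after the values were seen. Of 324 chromosome 10 genes detected on both arrays, 300 (92.6%) were lower, with a median of -0.80, a ratio of 0.576. Relative to all other genes the median was -0.77, and it was -0.51 without background correction and -0.24 with no detection filter. The genes of all other chromosomes had a median of -0.03 with 53.3% lower, and chromosome medians elsewhere ran from -0.12 to 0.041. Chromosome 10 held 3.46% of the genes detected on both arrays and 104 of the 239 such genes (43.5%) at least 2-fold lower, among them PYROXD2, LZTS2, MKI67 and BNIP3. In 13 consecutive blocks of up to 25 neighbouring genes, the block medians ran from -1.01 to -0.60, against -0.37 to 0.27 in 354 blocks elsewhere. The chromosome 10 gene NRP1, a neuropilin, was at least 2-fold higher (1.18), and NFKB2, an NF-kB subunit gene, stood at 0.98; both were chosen after their values were seen. Without chromosome 10, 239 genes were at least 2-fold higher and 158 lower, so that 60.2% were higher.

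**Figure D3:**
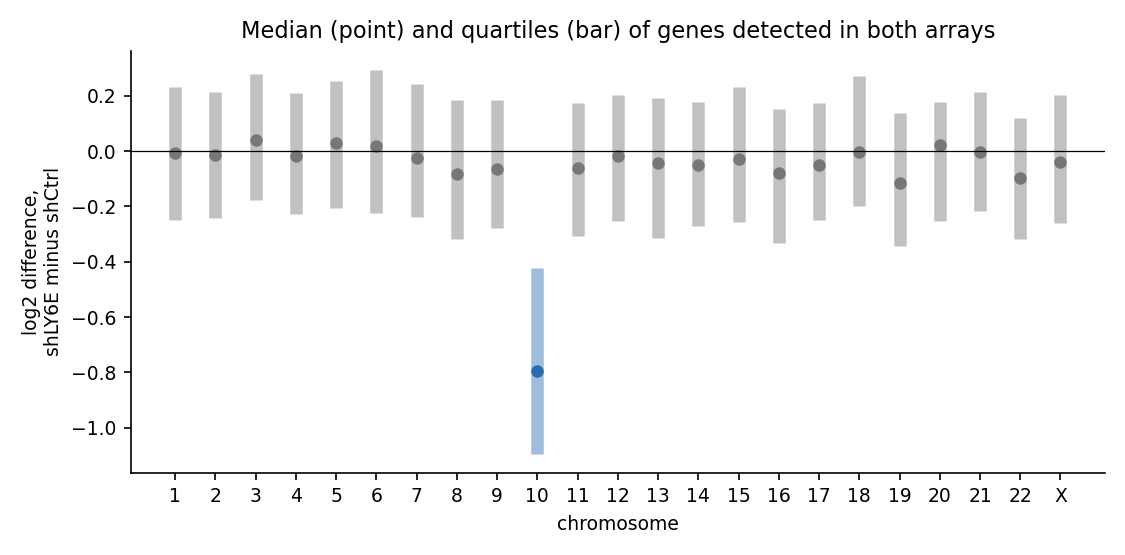
Log2 difference (shLY6E minus shCtrl, y axis) by chromosome (x axis) for genes detected on both arrays; points are medians and bars run from the lower to the upper quartile over genes. Chromosome 10 has a median of -0.80, and the other chromosomes lie between -0.12 and 0.041.

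Genes of glycolysis and the hypoxia response had a median of -0.21 at percentile 1.37 (-0.14 with median scaling), with 8 of 25 at least 1.5-fold lower and 1 higher. PFKFB4 was 2.65-fold lower and ALDOC 2.06-fold lower. BNIP3 and PGAM1, at 2.41-fold and 1.95-fold lower, are among 6 members on chromosome 10, which were all at least 1.5-fold lower. Without these 6 the median was 0.036, at percentile 80.5. In the authors' processed intensities the full list stood at percentile 2.69.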

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

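The platform annotation used here lists no gene for 17200 probes, and the comparison by gene left these out. Of 3846 such probes detected on at least 1 array, 61 were at least 2-fold higher and 36 at least 2-fold lower in shLY6E, against 240 and 269 of the 10565 genes. The largest log2 difference among these probes was 4.79 and the lowest -2.62. Which transcripts they read was not analysed here, so they may read genes described above or others. No explanation was tested.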

How the results depend on the processing

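LY6E was lower under all 8 settings fixed beforehand, and none (0) of the 68 other named genes at least 2-fold apart changed direction under any setting that gave them a value; 19 were under 2-fold without background correction and 8 with offset 50. The counts of genes at least 2-fold higher and lower were 97 and 65 without background correction, 144 and 129 with offset 50, and 158 lower without chromosome 10; elsewhere they stayed within 1.5 times the main counts. The genes counted without background correction or with offset 50 were all among the main ones, and both settings shrink differences by construction. Without background correction LY6E stood at -1.55, and the medians were 0.13 for CD14 and TLR4 signalling, -0.25 for interferon-stimulated genes, 0.82 for inflammatory and NF-kB genes and 0.21 for monocyte markers. With offset 50 the last 3 were -0.33, 0.998 and 0.28. With median scaling the CD14 and TLR4, inflammatory and monocyte medians were 0.32, 1.56 and 0.59. With a detection p-value under 0.05 the first 2 of these were 0.32 and 1.60, and with measured differences in place of bounds 0.32 and 1.69. The inflammatory median was 1.20 without a detection filter and 1.52 as the mean over probes. Except where said, the cause was not tested. The glycolysis median changed sign, to 0.036, without its chromosome 10 genes. Some of the 13 lists outside the central 95% of random lists share members, so they are not independent. Of the 13 lists, 8 stayed outside under every setting. Besides the glycolysis list, those that did not were immature myeloid genes (percentile 20.03, without a detection filter), GPI-anchored proteins (lowest percentile 94.7, without background correction), adhesion molecules (91.2, detection on both arrays) and the unfolded protein response (97.1, without background correction). The chromosome 10 median relative to other genes was -0.77, and -0.51 without background correction, -0.63 with offset 50 and -0.24 without a detection filter. Leaving out chromosome 10 and using measured differences were chosen after seeing the data. Background limits dim genes: the median intensity of detected probes was 2.27 times the background in shLY6E and 2.64 times in shCtrl. No paired analysis was possible because each group had 1 array.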

Other observations

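Of 15 detected GPI-anchored leukocyte surface proteins, 5 were at least 1.5-fold higher and 1, LY6E, was lower, with a median of 0.28 at percentile 99.5. Without background correction this median was 0.089, inside the central 95% of random lists at percentile 94.7, and it was also inside with offset 50 and without a detection filter. CD52, a small lymphocyte and monocyte antigen, was 2.5-fold higher and PRNP, which encodes the prion protein, 2.05-fold. Of 19 adhesion molecules and chemokine receptors, 7 were at least 1.5-fold higher and 1 lower, with a median of 0.18 at percentile 99.1. Over genes detected on both arrays it was 0.10, inside the central 95% at percentile 91.2, and it was also inside with median scaling and offset 50. The integrin genes ITGAL and ITGB7 were 3.07-fold and 2.23-fold higher, ICAM1 was at least 2.80-fold higher, and ITGB1, on chromosome 10, was 2.09-fold lower. In the list of lipid handling and LXR or PPAR targets, 5 of 18 were at least 1.5-fold higher, 12 were within 1.5-fold, and the median of 0.11 lay inside the central 95% of random lists, at percentile 92.9 (0.20 and 97.8 with median scaling, 0.045 and 84.4 without background correction). Among its members, the lipoprotein lipase gene LPL was 5.33-fold higher, PPARG 2.54-fold, the cholesterol exporter gene ABCA1 1.89-fold and PLIN2 1.88-fold. Cholesterol biosynthesis had a median of -0.083 at percentile 32.2, and IDI1, on chromosome 10, was 2.22-fold lower.

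Immediate early genes had a median of 0.050 at percentile 83.9 (0.13 with median scaling), though JUN was 3.13-fold higher. Heat shock genes had a median of -0.076 at percentile 38.9 (-0.022 averaged over probes), with HSPA6 5.78-fold higher and BAG3, on chromosome 10, 2.21-fold lower. The unfolded protein and integrated stress response had a median of 0.16 at percentile 98.3, but lay inside the central 95% without background correction (97.1) and with median scaling (97.3), with ATF3 1.58-fold higher, VLDLR 1.71-fold lower and DDIT4, on chromosome 10, 1.72-fold lower. For p53 targets the median was 0.030 at percentile 74.8 (-0.015 with median scaling). Of 17 detected members, 5 were at least 1.5-fold lower, 2 at least 1.5-fold higher and 10 within 1.5-fold. CDKN1A, a cell cycle inhibitor gene, was 1.68-fold lower. Cytosolic ribosomal proteins had a median of 0.083 at percentile 99.8, which was 0.30 with median scaling, with RPL14 1.71-fold higher and 36 of 37 within 1.5-fold. Oxidative phosphorylation stood at -0.064 and percentile 34.6 (-0.012 with median scaling), RNA interference machinery at -0.072 and percentile 38.01 (-0.039 with detection p under 0.05), and common reference genes at 0.038 and percentile 80.3 (0.14 with median scaling), the last 2 with 0 genes beyond 1.5-fold by their brightest probe. The other probe of the reference gene YWHAZ gave 1.30. HIV host and restriction factors stood at 0.042 and percentile 78.0 (0.013 averaged over probes), with SAMHD1 at least 2.26-fold higher and MX2 2.31-fold lower. Of the lists of other cell types, the erythroid and megakaryocyte list had 4 detected genes and a median of 0.043 at percentile 63.8 (-0.019 over genes detected on both arrays). Detected B cell markers were CD79A and CD79B (2 genes), the T and NK cell marker was NKG7 (1 gene, 3.39-fold higher), and the epithelial marker was CLDN7 (1 gene, 1.51-fold lower).

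The 11 tests of explanations in the paragraphs that follow, and the bounds they used, were chosen only after the results were seen. For the lower chromosome 10 genes, background correction or normalization was tested as the whole cause. The median relative to other genes stayed between -0.78 and -0.51 over the settings that changed these steps. These steps acted on intensity and not on chromosome, and no setting left out normalization. The test could therefore hardly have turned out otherwise and decides little. The value closest to the bound of -0.2 used was -0.24. It came without a detection filter, a setting that keeps both steps and counts undetected genes too. The tables argue against a few regulated regions, since the highest median of a block of neighbouring genes was -0.60. They argue against a chance draw of genes of this intensity as well, since the median stood at percentile 0 of 10000 random sets. A copy number difference of the whole chromosome between the 2 cell lines is a candidate explanation: 92.6% of its genes were lower, every block was shifted, and the medians of other chromosomes stayed between -0.12 and 0.041. DNA was not analysed here, so this remains a hypothesis, and such a difference could have arisen in either line.

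For the higher inflammatory and NF-kB genes, background correction or normalization was likewise tested as the whole cause. The list median stayed above the central 95% of random lists in every setting. Its size depended on the setting, and the lowest value, without background correction, was 0.82 against an upper limit of 0.075. The random lists were matched on intensity within each setting, and no setting left out normalization, so this test also decides little. Lymphoid, erythroid or epithelial cells in the shLY6E sample stay open. Of 48 of their markers with a probe, 8 were detected in shLY6E and 6 in shCtrl. This difference of 2 does not bound a small share of such cells. Of the 6 detected on both arrays, NKG7 was 3.39-fold higher, and CD79B and CLDN7 were 1.77-fold and 1.51-fold lower. GP9, PPBP and GP1BA lay between -0.13 and 0.11. Single probes misreading is argued against only for CXCL8, IL1RN and SOD2, the 3 of the 17 listed genes at least 2-fold higher that had another detected probe, since 100% of those probes were at least 1.5-fold higher; over all 5 listed genes with another probe, whatever their difference, it was so for 4, and for the 14 genes with 1 probe this stays open. Culture or array differences unrelated to the shRNA cannot be told apart from LY6E silencing with arrays per cell line at 1, and the same holds for effects of the shRNA on other transcripts and for the chromosome 10 difference. LY6E silencing stays open as the biological explanation.

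For the lists lower in shLY6E, chromosome 10 members could account for the glycolysis and hypoxia list, whose median without them was 0.036. They do not account for the mitosis list, at -0.36 without them, or the interferon-stimulated list, at -0.40. Indirect effects of chromosome 10 genes on genes elsewhere were not tested.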
